A study of Homo sapiens with 2 samples.

How the data were processed

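Gene expression was measured by RNA sequencing of total RNA from Huh7 cells 2 days after siRNA transfection, with 1 library from cells given a control siRNA and 1 from cells given an siRNA against SRSF2. The sample titles name an siRNA, while the genotype label of the second sample reads as a knockout. The sample is treated here as an siRNA knockdown, as its title and protocol describe. RNA was extracted with Trizol and sequenced on a HiSeq2000 instrument, per the labels. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped reads of each library), with a column per library. The submitters' processing notes name Bowtie 0.12.2 and hg19. The program that counted reads, the annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here.

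The table held 40203 genes with a symbol and 25332 blank rows, which were left out. No symbol was repeated, and 26 symbols had been turned into dates by a spreadsheet program and belong to no list. There were 0 columns of unmapped samples. FPKM values are not counts, so no count test was run. The depth was read from the commonest nonzero values of tRNA genes, whose ratio was that of lengths of 73 and 72 bases. The step of 1 read then gave 26642817 mapped reads for the control library and 26854948 for the SRSF2 siRNA library. With these totals, 15 of 18 values of mitochondrial genes came out as multiples of 0.25 reads within 0.01 reads, so some reads had been divided. A length between 50 and 30000 bases that gave whole reads in both libraries, within 0.0001 reads, was found for 12334 of the 13697 genes compared (90.0%). Divided reads can also come out whole at a multiple of the true length, so this share does not count genes without divided reads. Approximate reads per gene used the smaller of this length and the longest annotated transcript. The 95% interval of each FPKM ratio is an exact (Clopper-Pearson) binomial interval on these reads and covers counting error only. An error in the length alters the width of an interval.

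Choices were fixed before the data were examined unless stated otherwise. The change of a gene was log2((FPKM + 1) in the SRSF2 siRNA library / (FPKM + 1) in the control library), for genes with an FPKM of at least 1 in a library. Folds of single genes in the text are ratios of the FPKM values without the pseudocount. Genes with a change of at least 1 or at most -1 were counted as 2-fold higher or lower, with no test, since 1 library per group gives no replicate error. For 40 gene lists on RNA processing, liver function, metabolism, stress, the cell cycle and other cell types, the median change of the measured members was compared with the medians of 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. Lists with fewer than 5 measured members have no percentile. The central 95% runs from percentile 2.5 to 97.5. The mitochondrially encoded list holds 26 symbols because alternate names of its 13 genes were entered.

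The genes named are SRSF2 and the SR protein list, the 12 highest and 12 lowest protein-coding genes by change with an FPKM of at least 5 in a library, up to 4 members of each described list with the largest absolute change, and the 5 genes with the highest mean FPKM. Genes named outside this rule are said to be, and some genes that the rule takes are not reported here. Exon overlaps, transcript length, GC content and 3' UTRs came from GENCODE release 29 on GRCh38, matched by accession or symbol. The FPKM table has no coordinates, and none were carried over from hg19.

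The alternatives chosen in advance were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, rescaling to a median ratio of 1, rescaling to a common total without the 50 most abundant genes, and quantile normalization. After the data were seen, a condition that the counting interval exclude 1 and the removal of a least-squares trend over GC content and transcript length were added. That trend covered 12153 genes (88.7%) and explained 3.27% of the variance of the change. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

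The procedure was tested on simulated data for this comparison. Of genes changed 1.5-fold, 2.5-fold and 4-fold, it called 6.25% of 64, 65.7% of 67 and 94% of 67 as 2-fold changed, and it called 0.308% of 11690 unchanged genes. A list of 20 genes shifted by -0.5 had a median of -0.434 below all random lists, and 9 of 100 unshifted lists fell outside the central 95%. The simulation holds counting error and a set random spread of each gene in each library. That spread was not measured from cultures, so the real difference between cultures is not covered. The 0.308% is therefore no estimate of the share of unchanged genes called in the real libraries.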

Results

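RNA from Huh7 cells, an established human hepatocellular carcinoma line, was sequenced 2 days after transfection with a control siRNA or with an siRNA against SRSF2, a serine/arginine-rich (SR) protein that takes part in pre-mRNA splicing. There were 2 libraries, 1 per group. The deposited values were FPKM for 40203 genes, of which 13697 had an FPKM of at least 1 in a library and entered the comparison. The size of 1 read in the FPKM values of tRNA genes corresponded to 26642817 mapped reads in the control library and 26854948 in the SRSF2 siRNA library. With 1 library per group, no difference below has a replicate check, and no p-values are given. The 95% intervals in parentheses are exact binomial intervals for the ratio of approximate read numbers and cover counting error only, not the difference between cultures.

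The comparison asks how the transcriptome of these cells differs when SRSF2 is depleted. SRSF2 itself was 5.82-fold lower (5.47 to 6.18), at 91.4 FPKM in the control library and 15.7 FPKM in the SRSF2 siRNA library. The gene lies on chromosome 17 at 76734115 to 76737374 on the minus strand of GRCh38 and shares exon sequence there with MFSD11 on the plus strand. The value of MFSD11, which was looked at after the result for SRSF2 was seen, was 14.1 FPKM in the control library and 4.11 in the SRSF2 siRNA library. Whether reads were assigned by strand is not given in the sources used here, so reads from the shared sequence may be counted for either gene. Most transcripts of the other SR proteins differed little. None of the 13 listed members was 2-fold higher or lower on the log2(FPKM + 1) scale, their median log2 change was 0.01, and their mean was -0.07. SRSF1 stood at 73.3 and 75.2 FPKM, SRSF3 at 115 and 116, and SRSF7 at 86.9 and 78.6 in the control and SRSF2 siRNA libraries. SRSF9 stood at 87.6 and 105 FPKM, and SRSF12, a member of low abundance, was 2.76-fold lower (2.21 to 3.46) as a ratio of FPKM values, at 3.17 and 1.15 FPKM, with a log2 change of -0.96 on that scale. The median of the SR protein list changed sign under 2 of the 3 other scalings, and no direction is given for it.

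Across the 13697 genes, 230 (1.68%) were at least 2-fold higher and 333 (2.43%), SRSF2 included, at least 2-fold lower in the SRSF2 siRNA library on the log2(FPKM + 1) scale, and 13134 lay within 2-fold. This scale understates the change of genes with low values. With a pseudocount of 0.1 the counts were 503 and 750, and with a pseudocount of 5 they were 50 and 70. The change had a median of -0.01 over all 13697 genes, and its 5th and 95th percentiles were -0.79 and 0.70.

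**Figure D1:**
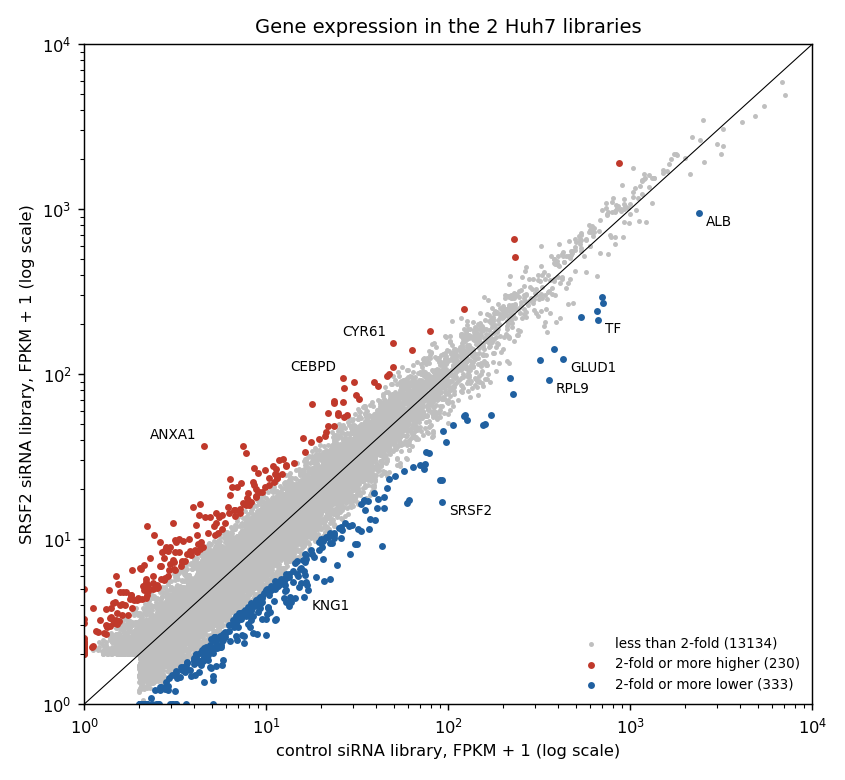
FPKM + 1 of 13697 genes in the control siRNA library (x axis, log scale) and the SRSF2 siRNA library (y axis, log scale), with 1 point per gene and the line of equal values. Red points are the 230 genes at least 2-fold higher and blue points the 333 genes at least 2-fold lower in the SRSF2 siRNA library, among them SRSF2 at 91.4 and 15.7 FPKM.

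After SRSF2, the protein-coding genes with the largest negative change included several metabolic enzymes. ACAT1, a mitochondrial acetyl-CoA acetyltransferase, was 4.56-fold lower (3.78 to 5.54), and SQLE, the squalene epoxidase of cholesterol synthesis, 3.77-fold lower (3.54 to 4.02). GLUD1, the mitochondrial glutamate dehydrogenase, was 3.48-fold lower (3.40 to 3.56) at a high level, 425 FPKM in the control library and 122 in the SRSF2 siRNA library. RPL9, a protein of the large ribosomal subunit, stood at 355 and 90.9 FPKM, 3.90-fold lower (3.79 to 4.02). Its reads can be shared with near-identical pseudogene copies, and its exons overlap those of LIAS on the opposite strand. Also among the 12 lowest were HGSNAT (4.58-fold lower), KNG1 (4.37-fold lower), ZDHHC24 (4.27-fold lower), SLC6A6 (3.93-fold lower) and TST (3.68-fold lower). Exons of ZDHHC24, SLC6A6 and TST overlap those of a gene on the opposite strand.

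The 12 protein-coding genes with the largest positive change included genes for secreted, matrix and signalling proteins. ANXA1, a calcium-dependent phospholipid-binding protein, was 10.1-fold higher (8.528 to 12.001), at 3.53 FPKM in the control library and 35.6 in the SRSF2 siRNA library. TXNIP, which binds thioredoxin, was 5.50-fold higher (4.99 to 6.05). The transcription factor gene CEBPD reached the highest level of the 12, with 93.6 FPKM against 25.4 in the control library, a ratio of 3.68 (3.41 to 3.98). KITLG, the ligand of the KIT receptor, was 6.61-fold higher (5.45 to 8.08) but low in both libraries, at 0.83 and 5.47 FPKM. The glutamate transporter gene SLC1A3 was 5.60-fold higher (4.58 to 6.90), the collagen gene COL12A1 5.33-fold higher (4.84 to 5.87), and the alkylation repair gene ALKBH3 5.15-fold higher (3.85 to 7.09). Also among the 12 were ZNF134 (4.95-fold higher), PALMD (4.76-fold higher), VNN2 (4.60-fold higher) and NABP1 (4.17-fold higher).

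Genes of lipid synthesis were lower as a group in the SRSF2 siRNA library. Of 23 cholesterol synthesis genes, 21 had lower and 2 higher values, 5 were at least 2-fold lower and none was 2-fold higher. Their median log2 change of -0.65, or 1.57-fold lower, lay below the medians of all 10000 random gene lists matched on expression. Besides SQLE, the genes at least 2-fold lower included NSDHL, a sterol dehydrogenase, at 36.3 and 12.3 FPKM in the control and SRSF2 siRNA libraries, and LSS, the lanosterol synthase, at 39.7 and 14.4 FPKM. Of 18 measured fatty acid and lipid synthesis genes, 16 had lower and 2 higher values, and 6 were at least 2-fold lower. Their median of -0.74 also lay below those of all 10000 random lists, but was -0.38 with a pseudocount of 5, -0.46 with a filter of 5 FPKM and -0.49 after a trend over GC content and length was removed. The stearoyl-CoA desaturase SCD stood at 699 and 293 FPKM, 2.39-fold lower (2.36 to 2.42), and SREBF1, which encodes a transcription factor of lipid synthesis genes, at 72.1 and 25.5 FPKM, 2.83-fold lower (2.72 to 2.95). The fatty acid desaturases FADS2 and FADS1 were 3.01-fold and 2.54-fold lower, but the exons of these neighbouring genes overlap each other, and those of FADS2 also overlap FEN1.

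Transcripts of hepatocyte products were lower too. Of 24 measured genes for proteins that hepatocytes secrete, 20 had lower and 4 higher values, 5 were at least 2-fold lower and none was 2-fold higher, with a median of -0.55 that lay below all 10000 random lists. Albumin (ALB) stood at 2365 FPKM in the control library and 946 in the SRSF2 siRNA library, 2.499-fold lower (2.475 to 2.523). Transferrin (TF) was 3.15-fold lower (3.12 to 3.17), with 662 and 211 FPKM, and the fibrinogen gamma chain (FGG) 2.73-fold lower (2.67 to 2.79). Exons of TF overlap those of SRPRB and TFP1 on the same strand. Its approximate reads, 197009 in the control library against 141560 for ALB, rest on a much longer length. The interval of TF is too narrow if that length is too long. All 8 measured genes of gluconeogenesis and amino acid catabolism had lower values, with a median of -0.80 below all random lists and 3 genes at least 2-fold lower. ASS1 and ARG1 of the urea cycle were 2.24-fold and 2.96-fold lower. Only 8 of the 16 listed genes passed the filter on low values. The median was -0.37 with a pseudocount of 5, and with no filter it was -0.10 at percentile 2.66, inside the central 95% of random lists.

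Among 13 fetal liver and hepatocellular carcinoma markers the median was -0.26, at percentile 0.75. AFP, the fetal serum protein used as a marker of this cancer, was 2.61-fold lower (2.54 to 2.68), at 702 and 269 FPKM, and IGF2 was 1.75-fold lower (1.71 to 1.78). The 16 liver transcription factors had a median of -0.24, at percentile 1.65, but 2.73 with no filter on low values and 4.07 after a trend over GC content and length was removed. CEBPA was 3.20-fold lower (3.08 to 3.32), at 155 and 48.4 FPKM, and NR5A2 was 1.72-fold lower. Among markers of other cell types, 4 of 12 immune cell markers were measured, with LYZ 2.79-fold higher (2.35 to 3.32) and CD14 at 27.0 and 34.3 FPKM. LUM, the 1 measured endothelial or stellate cell marker, was 3.02-fold higher (2.86 to 3.20), at 29.5 and 89.0 FPKM. Of the non-liver epithelial and neural markers 2 were measured, CDX2 at 10.7 and 4.86 FPKM and MBP at 3.49 and 3.05 FPKM.

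Stress and growth control genes differed in both directions. Of 18 measured immediate early genes, 12 had higher and 6 lower values, and 4 were at least 2-fold higher. Their median of 0.43 lay at percentile 99.99 and was 0.25 with no filter on low values. CYR61, a matrix-associated signalling protein, was 3.13-fold higher, at 48.9 and 153 FPKM, and MYC was 2.33-fold higher (2.13 to 2.56), at 10.2 and 23.9 FPKM. FOS was 9.11-fold higher (4.88 to 18.8), but at only 0.19 and 1.74 FPKM. Targets of p53 were lower, with a median of -0.25 over 22 genes at percentile 1.30 (2.61 after the GC content and length trend was removed). CDKN1A, the p21 cell cycle inhibitor, was 3.11-fold lower (2.52 to 3.86), and TP53INP1 was 2.53-fold lower (2.37 to 2.70). The 21 genes of the unfolded protein response had a median of -0.17 at percentile 2.26, and lay inside the central 95% with a filter of 5 FPKM and after quantile normalization. Within this list PPP1R15A was 2.91-fold higher (2.74 to 3.10) and ATF4 1.87-fold higher (1.81 to 1.93), while CHAC1 was 3.17-fold lower (2.22 to 4.62). The 14 measured ATF4 targets of the amino acid response had a median of -0.23 at percentile 1.58, but -0.087 at percentile 8.19 with no filter and -0.12 at percentile 7.39 after the trend was removed, with ASNS 1.80-fold lower and GDF15 1.80-fold higher. Interferon response genes had a median of -0.35 over 15 genes at percentile 1.62. This median was -0.056 at percentile 5.83 with no filter on low values, -0.18 with a pseudocount of 5 and -0.61 with a filter of 5 FPKM, and the percentile was 2.70 after quantile normalization. Of these 15 genes, 13 had lower and 2 higher values. OAS3 was 2.70-fold lower, at 4.20 and 1.56 FPKM, and MX2 was 2.68-fold higher, at 1.52 and 4.07 FPKM.

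Cell cycle lists moved apart. The 27 genes of DNA replication had a median of -0.18 at percentile 0.57, with MCM6, a helicase subunit, 1.54-fold lower (1.48 to 1.61) and ORC1 1.48-fold lower (1.34 to 1.63). The 26 genes of G2/M and mitosis had a median of 0.24 at percentile 97.8, or 96.5 after the GC content and length trend was removed. BIRC5 was 1.81-fold higher (1.61 to 2.03) and the mitotic kinase gene AURKA 1.56-fold higher (1.47 to 1.65). No gene of either list was 2-fold higher or lower.

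Of 34 core spliceosome genes, 29 had higher and 5 lower values, none by 2-fold, and their median of 0.28 lay at percentile 99.7. SF3B2, a component of the U2 particle, stood at 54.2 and 83.5 FPKM, and PRPF31 at 19.5 and 28.9 FPKM. Of 44 cytosolic ribosomal protein genes, 38 had higher and 6 lower values, with a median of 0.25 at percentile 98.5. RPL11 was 1.55-fold higher (1.52 to 1.59), and RPL9 was the 1 member past 2-fold, on the lower side. After quantile normalization the ribosomal median was 0.083 at percentile 72.6, and it also lay inside the central 95% with a filter of 5 FPKM and after the trend was removed. Of 13 mitochondrially encoded genes, 11 had lower and 2 higher values, with a median of -0.37 at percentile 0.09, which became -0.17 at percentile 2.65 after quantile normalization. The 5 most abundant genes of the table were in this list, with ATP6 at 7088 and 4928 FPKM, COX2 at 6771 and 5865, ND4 at 5402 and 4179, COX1 at 4858 and 3656, and COX3 at 4112 and 3353. COX2 was higher, not lower, after quantile normalization. The 5 highest values of each library held 6.49% of the summed FPKM in the control library and 4.97% in the SRSF2 siRNA library. In the SRSF2 siRNA library EEF1A1, at 3455 FPKM, took the place of COX3 among them.

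The other 21 lists with a percentile lay inside the central 95% of random lists, between percentile 3.47 for the TGF-beta and Wnt targets and 97.0 for the metallothioneins. Within the TGF-beta and Wnt list, whose median was -0.23, the BMP-responsive genes SMAD6 and ID1 were 4.09-fold (3.61 to 4.64) and 2.70-fold (2.61 to 2.79) lower. The glycolysis and hypoxia list had a median of -0.06, with NDRG1 3.55-fold lower (3.28 to 3.84) and ALDOC 2.53-fold lower (2.38 to 2.69). The fatty acid oxidation and ketogenesis list had a median of -0.19. Bile acid synthesis and transport genes had a median of -0.20, which was -0.064 with a pseudocount of 5 and 0.0065 with no filter on low values. Xenobiotic metabolism genes had one of 0.08 with a mean of -0.02, where SULT2A1 was 3.21-fold lower (2.93 to 3.51) and CYP1A1 2.43-fold higher (2.16 to 2.73). Apoptosis regulators had a median of -0.11, with BCL2L11 2.23-fold lower and BIRC3 2.88-fold higher. Among lists of RNA metabolism, the medians were 0.11 for hnRNP proteins, -0.26 for the SR protein kinases and CLK kinases, 0.19 for nonsense-mediated decay factors, 0.25 for the P-TEFb and 7SK complex, and -0.0037 for the RNAi pathway. Heat shock proteins had a median of 0.25, with HSP90AA1 at 321 and 600.0 FPKM, and metallothioneins one of 0.36. The medians were 0.09 for oxidative stress genes, 0.18 for NF-kB and inflammatory genes, 0.13 for extracellular matrix genes, 0.19 for nuclear oxidative phosphorylation, -0.09 for DNA damage repair and 0.08 for reference genes. Only 6 of 29 replication-dependent histones were measured, with a median of 0.31 that was 0.15 with a pseudocount of 5 and 0 with no filter on low values. Of these 21 medians, 18 moved by over 1.5 times or changed sign under at least 1 of the 8 alternatives, and 5 changed sign (SR proteins, bile acid, glycolysis and hypoxia, oxidative stress and RNAi pathway), so no direction is given for these 5. Across the 37 lists with a percentile, 12 lay below and 4 above the central 95% of random lists, where 1.85 would be outside by chance if lists were independent random draws. On simulated data 9 of 100 unshifted lists fell outside, so the nominal rate may be too low, though 100 lists do not fix the rate closely. The percentiles describe these 2 libraries and do not test the condition.

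**Figure D2:**
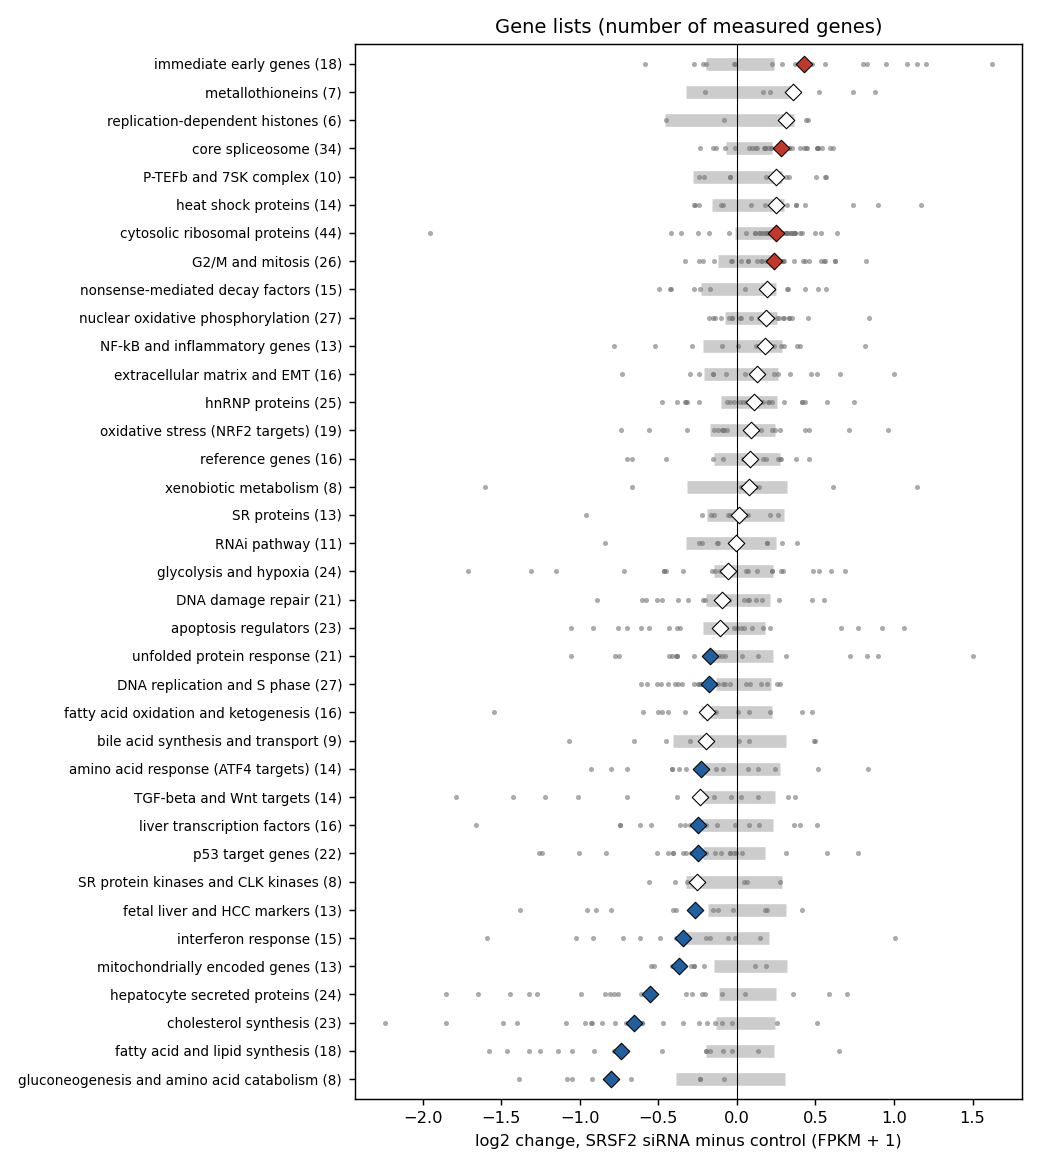
Log2 change of (FPKM + 1), SRSF2 siRNA minus control (x axis), for the 37 gene lists with a percentile, with 1 dot per gene, a diamond at each list's median, and a grey bar for the central 95% of the medians of 10000 random lists. Diamonds are blue for the 12 lists below the bar, red for the 4 above it and white for the rest, from -0.80 for gluconeogenesis and amino acid catabolism to 0.43 for immediate early genes.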

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

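The alternatives that remove a trend over GC content and transcript length or require a counting interval that excludes 1 were chosen after the data were seen. No paired analysis was possible because there was 1 library per group, and for the same reason no library could be left out. The count of 230 higher and 333 lower genes depended on how low values were treated. It was 503 and 750 with a pseudocount of 0.1, 50 and 70 with a pseudocount of 5, and 145 and 214 with a filter of 5 FPKM, where fewer genes could enter. Under the 3 other scalings it was 236 and 329 (median ratio), 193 and 387 (common total without the 50 most abundant genes) and 259 and 293 (quantile normalization). Among the 12153 genes with a length and GC content it was 190 and 300 before and 194 and 257 after the trend was removed. Of all 230 and 333 genes, 199 and 284 had a counting interval that excluded 1. The log2 change of SRSF2 was -2.47, and -2.22 with a pseudocount of 5, which pulls in every change by construction. No median of the 16 lists outside the central 95% changed sign under the 8 alternatives. For the pseudocounts and the rescalings by a constant this was nearly fixed in advance. The interferon response median was -0.056 with no filter, where unexpressed members enter. The mitochondrially encoded median was -0.42 with a common total without the 50 most abundant genes, -0.17 after quantile normalization and -0.44 after the trend was removed, and the ribosomal protein median was 0.083 after quantile normalization. The common total divided all SRSF2 siRNA values by 1.03, which lowers every change by about the same amount and gives the -0.42 by construction. The cause of the other shifts of the mitochondrial and ribosomal medians was not tested. Of the 16 lists, 7 stayed outside the central 95% under all 8 alternatives: hepatocyte secreted proteins, cholesterol synthesis, fatty acid and lipid synthesis, DNA replication, fetal liver and carcinoma markers, core spliceosome and immediate early genes. The other 9 came inside under at least 1. Rescaling to a median ratio or to a common total shifts listed and random genes alike. Those alternatives could hardly move a percentile and are no check of it. No named gene with a change of 2-fold or more changed sign. A pseudocount or a filter cannot alter the sign of a gene's change. The rescalings to a median ratio and to a common total divided all SRSF2 siRNA values by only 0.992 and 1.03. Only quantile normalization and removal of the trend could have reversed such a gene. The planned choice between rows of a repeated symbol was not run, since no symbol was repeated. Depth limits single genes of low abundance, and the missing replicates limit every comparison.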

Other observations

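In the results that follow, the families by gene symbol, the scan of short sites, the tests on GGAGAA that followed from it and the test of the other ribosomal protein genes were chosen after the results they bear on were seen. Grouping genes by the letters that begin their symbol gave 56 families of at least 20 measured members, of which 10 lay above and 6 below the central 95% of random lists. Mitochondrial ribosomal protein genes were higher in the SRSF2 siRNA library. Of 48 MRPL genes 44 had higher values, with a median log2 change of 0.32, and of 32 MRPS genes 24 did, with a median of 0.29. MRPS34 stood at 54.8 FPKM in the control library and 110 in the SRSF2 siRNA library, and MRPL52 at 48.6 and 95.9, while MRPS16 went the other way, at 30.9 and 15.4 FPKM. RNA polymerase subunit genes (POLR, 30 genes) had a median of 0.22, with POLR2C at 44.0 and 82.6 FPKM but POLR2A, the largest subunit of RNA polymerase II, at 60.0 and 36.6 FPKM. The 21 genes of the TAF prefix had a median of 0.33. These medians kept their sign under the 3 other scalings, of which only quantile normalization could have changed the sign of medians this large.

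Families of other symbols were lower. The 208 solute carrier (SLC) genes had a median of -0.28 below all 10000 random lists, and 13 were at least 2-fold lower and 2 at least 2-fold higher. SLC16A3, a lactate transporter, stood at 62.9 and 26.4 FPKM, the amino acid transporter SLC38A3 at 15.7 and 4.25, and the bicarbonate transporter SLC4A4 at 1.09 and 4.22. The 166 TMEM genes had a median of -0.18 and the 23 KLHL genes one of -0.35. Both signs held under the 3 other scalings, of which only quantile normalization could have changed them. Single genes outside the rule for names with large changes at high abundance, all chosen after their values were seen, were KRT18, a keratin of simple epithelia, at 865 and 1901 FPKM, TPM4, a tropomyosin, at 228 and 659 FPKM, and GJA1, connexin 43, at 233 and 510 FPKM.

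The cholesterol synthesis, fatty acid synthesis and hepatocyte secreted protein lists were lower together. The highest of the 3 medians was -0.49 after a trend over GC content and transcript length was removed, which argues against that trend as the cause. A scan of 15378 sites of 7 bases in the 3' UTRs of 10742 genes, meant to find a seed match of the SRSF2 siRNA, whose sequence is not given in the sources used here, was led by GATTTGG (z = -5.38 for the mean change of genes with the site, against a lowest z of -4.92 in 100 shuffles). The 59 of 64 list members without that site had a median of -0.61. Matches to it in their own 3' UTRs therefore do not account for the lower values of these 59. Effects of a match in another gene and other off-target effects were not tested, and the true seed is not known. An effect of SRSF2 depletion and a chance difference between single cultures, with 1 library per group, cannot be told apart.

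RPL9 was 3.90-fold lower while the other 43 ribosomal protein genes had a median log2 change of 0.25, which argues against a loss shared by ribosomal protein genes. Its pseudogene copies can share its reads, and RPL9P8 and RPL9P9 stood at 91.3 and 89.4 FPKM in the control library and 22.0 and 21.9 in the SRSF2 siRNA library. The sum over RPL9 and its copies was 3.94-fold lower, which argues against reads moving from the gene to its copies. LIAS, whose exons overlap RPL9 on the opposite strand and which was looked at after the result was seen, stood at 3.71 and 6.22 FPKM. Why RPL9 was lower stays open, and neither SRSF2 depletion nor an off-target match of an siRNA was tested as its cause.

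The 382 measured zinc finger genes with ZNF symbols were higher as a family, with a median log2 change of 0.22, above all 10000 random lists, and 273 of them had higher values. After the GC content and length trend was removed the median was still at percentile 100, which argues against that trend, while reads shared between paralogs stay open, since divided reads can pass as whole in the 345 members with whole reads (median 0.20). The sites most tied to higher values in 3' UTRs were AGGAGAA (z = 6.28, or 5.38 in a scan without ZNF genes, where GATTTGG had -5.92) and its neighbours. Genes with AGGAGAA in the 3' UTR had a median of only 0.018, and those without it -0.039, a small difference beside the family median. A seed match of the control siRNA, lowering the family's genes in the control library, is a candidate explanation. Within the family, GGAGAA was counted over the whole transcript, not the 3' UTR alone. The 24 family genes without GGAGAA had a median of -0.02, at percentile 59.3, and the 352 with it one of 0.24. Other protein-coding genes do not decide whether this explanation holds. Their median was -0.069 without GGAGAA, -0.026 with it and -0.00064 for the 1700 with at least 5 sites. For these 1700 it was 0.063 after the trend was removed, above random lists but below the 0.32 of the 189 family genes with as many. GGAGAA can encode part of the linker between zinc fingers, so the family genes without it may differ in kind, and an effect of SRSF2 depletion stays open.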
